A study of Oryzias latipes with 26 samples.

How the data were processed

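RNA from medaka testes was hybridised to Agilent oligonucleotide arrays (60-base probes) and measured in 1 colour. The 26 arrays made 9 groups, with the pooled testes of 1 beaker per array as the replicate.

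The scanner files hold one row per spot. Per the file headers they were written by Feature Extraction 10.5.1.1, while the processing notes of the submitters name version 8.1. The processed signal, the spot mean and the local background are intensity values on a linear scale, background-subtracted in the first case, as deposited. Each spot also has other columns deposited by the authors, flags of 0 or 1 for signal well above background, non-uniformity and saturation. The value table of the series holds a score per probe and sample, deposited as log values that the authors scaled to a mean of 0 and an SD of 1 in each column.

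Control spots and spots flagged as outliers were left out, and spots of the same probe were averaged. The log2 of the processed signal was taken minus the 75th percentile of the array over all non-control probes. A probe was tested if it was well above background on every array of at least 1 group, which left 12118 probes. Of these, 8093 were well above background on all arrays. The median residual SD of a probe was 0.385 log2 with 17 residual degrees of freedom. It was 0.309 with 16 under the value-table assignment, which has the same sets of arrays without the low-signal one.

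Arrays were given to samples in 3 ways. The scanner-file assignment follows the sample record to which each file is attached. Each column of the value table was also correlated with the log signal of every scanner file, and 25 columns matched exactly 1 file at a Pearson r of 1 to 3 decimals across probes. The value-table assignment gives these arrays the sample of the matching column. The third set was the 9 arrays with the same sample in both records. The first assignment, its comparisons, the gene lists and the alternatives were fixed before the data were examined, and the other 2 were added after the files were seen.

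One linear model per assignment (limma 3.58.1, R 4.3.3) held a mean for each group. Each dose was compared with the control of the same day, with the other dose, and over time as the effect on day 14 minus that on day 1. The mean effect over days and the control groups of days 7 and 14 against day 1 were also tested. Variances were moderated by eBayes, p-values were adjusted by the Benjamini-Hochberg method over all tested probes, and the threshold was 0.05. All tests were two-sided. Where a group was not well above background on every array, each value of the lower group was raised to at least the lowest signal well above background on its array. The ratio of the group means is then given as a lower bound (at least).

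Probe names were taken from the arrays. Most were Ensembl gene identifiers (15118 probes of medaka and 19 of stickleback). The reference table held 26845 genes, 0 of them with an Ensembl identifier, and gave a name to 0 of 12058 tested probes with such a name. Named genes were therefore the 70 probes with nuclear receptor names, of which 51 were tested. The brightest tested probe of identical sequence stood for each name (39 names had a second probe). Counts over these names alone were made after the names were seen.

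Genes were named by a fixed rule. In each comparison with control it took the 5 highest and 5 lowest passing genes whose arrays did not overlap, up to 4 passing members of each list, and a fixed set that included ER-A. Other contrasts took up to 3 genes each way, and where none passed, the 3 with the smallest p. At most 2 unnamed probes each way were added, and PR was added after its values were seen.

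Of 22 gene lists, only that of hormone receptors had at least 5 tested members (16) and was tested with camera (preset correlation 0.01, also estimated) and fry. The steroidogenesis list had 2 (SF1-1, SF1-2), the Sertoli cell list 1 (DAX), the Leydig cell list 2 (TR3-1, TR3-2), the xenobiotic list 1 (PXR) and the retinoid list 4 (RAR-A, RXR-B1, RXR-B2, RXR-G). The lists of egg proteins, oocyte, matrix, spermatogonia, meiosis, spermatid, apoptosis, cell cycle, leukocyte, complement, hepatocyte, erythrocyte, muscle, endothelial, cholesterol and stress genes had 0 and gave no result.

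Alternatives changed 1 choice at a time, except that the values of the value table also brought their own scaling, the samples of the column headers and the unmatched column in place of the low-signal array. They were normexp background correction (offset 50), median scaling, quantile normalization, the values of the value table, no filter or a stricter filter on dim probes, array weights, a trended and robust variance, and fits of only the groups compared. Further ones were the slide as a fixed or random block, the replicate number as a block, the mean of all probes of a gene, and leaving out each array. Up to 100 other splits of the arrays were drawn for comparisons of groups with at least 3 arrays, and for the means over days.

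The model was tested on simulated data with the group sizes and residual spread of the arrays, with 100 probes changed by each of log2 1 and log2 2. For EE2 10.0 µg/L on day 14, 33% and 76% of them passed, with 6 false calls. On day 1, with 2 exposed arrays, 31% and 69% passed, with 9 false calls. For EE2 1.0 µg/L on day 1, 38% and 81% passed, with 14 false calls. No call had the wrong sign.

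Files were read with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), random blocks used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9. The unmatched column was used only in the alternative with the table values. Some probes picked by the rules for naming are not reported here, and no others took their place. Ensembl gene names, gene functions and other scanner columns were not used here.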

Results

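Ethinylestradiol (EE2), a synthetic estrogen, was given in the water to adult male medaka (Oryzias latipes), and testis RNA was measured on Agilent arrays in 1 colour (Cy3) after 1, 7 or 14 days. The design asked how testicular gene expression changes with EE2 dose and with time. The labels give 26 arrays in 9 groups: vehicle control (DMSO), EE2 1.0 µg/L and EE2 10.0 µg/L on each day. Each group had 3 arrays, except EE2 10.0 µg/L on day 1, which had 2. Each array carried RNA of testes pooled within 1 beaker, so the beaker was the replicate. Between 10744 and 12487 probes were well above background on 25 of the arrays. The remaining array, attached to the control of day 14 (replicate 1), had 8423 such probes and a 75th percentile signal of 172.6, against 369 to 1198 on the other arrays. The number of arrays per group limits the precision of every comparison.

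The deposited records hold 2 different assignments of arrays to samples. In the value table of the series, 25 of 26 columns matched exactly 1 scanner file (Pearson r of 1 to 3 decimals over the probes of the array). Of these columns, 9 matched the file attached to the sample in the column header, and 16 matched the file attached to another sample. In all 25 matched columns the header followed from the sample of the file by exchanging dose rank and day at the same replicate number. Controls of days 7 and 14 in 1 record were EE2 1.0 and 10.0 µg/L of day 1 in the other. Against the control of day 1 these are the same contrasts but for the low-signal array, not second results. The column of the control of day 14 (replicate 1) matched no file (best r 0.985), and the low-signal scanner file matched no column. The 9 arrays with the same label in both records were those of the control of day 1, EE2 1.0 µg/L of day 7 and EE2 10.0 µg/L of day 14. Neither record was used to correct the other. Values are given below with the samples of the scanner files (scanner-file assignment, all 26 arrays) and with those of the value table (value-table assignment, 25 arrays). Where these differ, no effect of the treatment is established.

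**Figure D1:**
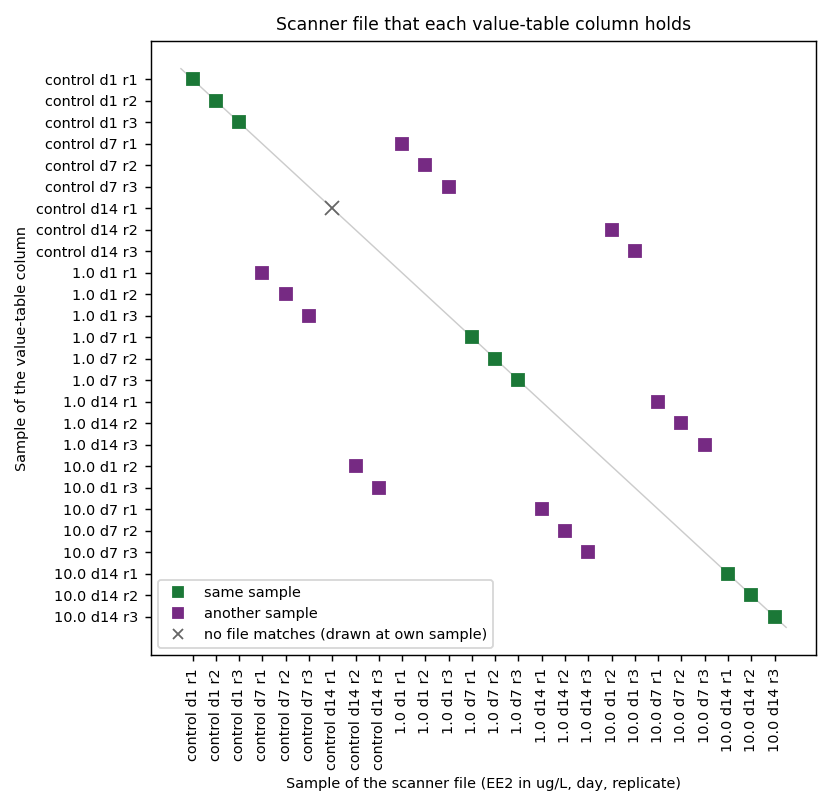
Each value-table column (vertical axis, sample of the column header) against the sample of the scanner file that it matched (horizontal axis), with EE2 in µg/L, day and replicate. Green squares on the line are the 9 columns that matched the file of their own sample, purple squares the 16 that matched the file of another sample, and the cross the column without a matching file.

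Most probes carry Ensembl gene identifiers that the files do not pair with gene names, and 70 probes carry names of nuclear receptors. Of these 70 names, 51 were measured well enough to be tested, among 12118 tested probes. Vitellogenin, choriogenin and the steroidogenic and testis genes of the fixed list of names could not be looked up by name, apart from estrogen receptor alpha (ER-A). Receptor names are given as on the array, values are log2 differences ± SE (adjusted over 12118 tests), and values in brackets after a replicate are those with that 1 array left out (EE2 1.0 and EE2 10.0 there being µg/L). For a probe that was not well above background on every array of a group, a lower bound of the fold is given (at least), after raising values of the lower group to at least the lowest signal well above background on their array. Opposite signs under another processing stand in brackets after the value, normexp being a background correction and the table values those of the value table. Counts are of probes with a limma adjusted p under 0.05.

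On the 9 arrays whose labels agree, testes of EE2 10.0 µg/L fish on day 14 differed widely from control testes of day 1. FF1C, a receptor of the FTZ-F1 family, was higher by 6.76 ± 0.41, a 108-fold difference (limma adjusted p 8.71e-05, n = 3 and 3). The small heterodimer partner SHP was at least 40.7-fold higher, being well above background on 3 of 3 exposed and 0 of 3 control arrays (limma adjusted p 2.57e-04). DAX-1 (DAX) was higher by 2.05 ± 0.27, the retinoid X receptor RXR-G by 1.86 ± 0.24 and the thyroid hormone receptor probe THR-A2 by 1.93 ± 0.53 (limma adjusted p 0.00109, 0.00103 and 0.0201). THR-A1, TR3-1 and RXR-B1 were higher by 1.34 ± 0.23, 0.93 ± 0.22 and 0.70 ± 0.18. The progesterone receptor PR was higher by 1.28 ± 0.20 (limma adjusted p 0.00208), a probe chosen after its values were seen. The steroidogenic factor 1 probes SF1-1 and SF1-2 changed by -1.02 ± 0.24 (0.25 with normexp) and -0.45 ± 0.14, and the photoreceptor-type receptor PNR-2 by -0.91 ± 0.27 (limma adjusted p 0.0107, 0.034 and 0.0244). PNR-1 was at least 2.03-fold lower (log2 0.50 with normexp), above background on 1 of 3 exposed arrays (limma adjusted p 0.019). ER-A did not pass (0.54 ± 0.29, limma adjusted p 0.167). PNR-1 lost its call without control of day 1, replicates 1, 3 or EE2 10.0 of day 14, replicate 1. PNR-2 lost its call without control of day 1, replicate 1 (-0.68) or EE2 10.0 of day 14, replicate 1 (-0.72). RXR-B1 lost its call without control of day 1, replicate 2 (0.60). SF1-2 lost its call without control of day 1, replicates 1, 2, 3 (-0.44, -0.44, -0.48), EE2 1.0 of day 7, replicate 2 (-0.45) or EE2 10.0 of day 14, replicates 1, 2 (-0.40, -0.47). THR-A2 lost its call without control of day 1, replicates 2, 3 (1.64, 1.91) or EE2 10.0 of day 14, replicate 1 (1.45).

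In all, 5176 probes passed in this comparison, 2793 higher and 2383 lower. Among the 51 receptor names 22 were higher and 4 lower (22 and 4 adjusted over the list alone). The split into higher and lower depended on scaling: it was 2151 and 3472 with median scaling and 2216 and 3107 with quantile normalization, with the median of all probes at 0.02, -0.22 and -0.15 respectively. The unnamed probes with the largest changes were ENSORLG00000011973 (at least 439.5-fold higher, above background on 2 of 3 control arrays), ENSORLG00000011980 (645-fold higher), ENSORLG00000008980 (at least 136-fold lower, above background on 0 of 3 exposed arrays) and ENSORLG00000019226 (at least 69.2-fold lower, on 1 of 3). Dose and day changed together in this comparison, and the exposed arrays lay on a slide of their own, so dose, duration and slide could not be separated.

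Testes of EE2 1.0 µg/L fish on day 7 had the same leading receptors. Against control testes of day 1, FF1C was higher by 3.53 ± 0.41, 11.6-fold, and SHP at least 6.73-fold higher, above background on 3 of 3 exposed and 0 of 3 control arrays (limma adjusted p 0.0111 and 0.0289, n = 3 and 3). ER-A was -0.83 ± 0.29 and did not pass (limma adjusted p 0.182). FF1C lost its call without control of day 1, replicate 3 (3.50) or EE2 1.0 of day 7, replicate 2 (3.45). SHP lost its call without control of day 1, replicates 1, 3, EE2 1.0 of day 7, replicates 1, 2, 3 or EE2 10.0 of day 14, replicate 2. Of the 51 receptor names these 2 passed, and 6 higher and 2 lower did when adjusted over the list alone. In total, 128 probes passed, 103 higher and 25 lower. Each of the 9 arrays moved that count by over 1.5 times when left out: control of day 1, replicates 1, 2, 3 (42, 26, 15), EE2 1.0 of day 7, replicates 1, 2, 3 (41, 17, 27) or EE2 10.0 of day 14, replicates 1, 2, 3 (393, 62, 225). Between the exposed groups, EE2 10.0 µg/L of day 14 exceeded EE2 1.0 µg/L of day 7 in FF1C by 3.23 ± 0.41, in SHP by 2.60 ± 0.55 and in RXR-G by 2.20 ± 0.24 (limma adjusted p 0.00164, 0.00719 and 0.00134). ER-A was higher there by 1.36 ± 0.29 (limma adjusted p 0.00748). PPAR-G, DAX, THR-A1 and THR-B were also higher, by 1.82 ± 0.25, 1.59 ± 0.27, 1.17 ± 0.23 and 0.93 ± 0.30, while PNR-2 and SF1-2 changed by -1.42 ± 0.27 and -0.73 ± 0.14. TR3-2 was at least 1.15-fold lower, above background on 0 of 3 against 2 of 3 arrays (log2 0.22 with normexp), and PNR-1 at least 1.96-fold lower, above background on 1 of 3 against 3 of 3 arrays (log2 0.14 with normexp). PNR-1 lost its call without EE2 1.0 of day 7, replicates 2, 3 or EE2 10.0 of day 14, replicates 1, 3. THR-B lost its call without control of day 1, replicates 1, 3 (0.93) or EE2 1.0 of day 7, replicates 1, 2, 3 (0.89, 0.91, 0.99). That comparison had 2762 higher and 2257 lower probes (1894 and 3272 with median scaling).

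**Figure D2:**
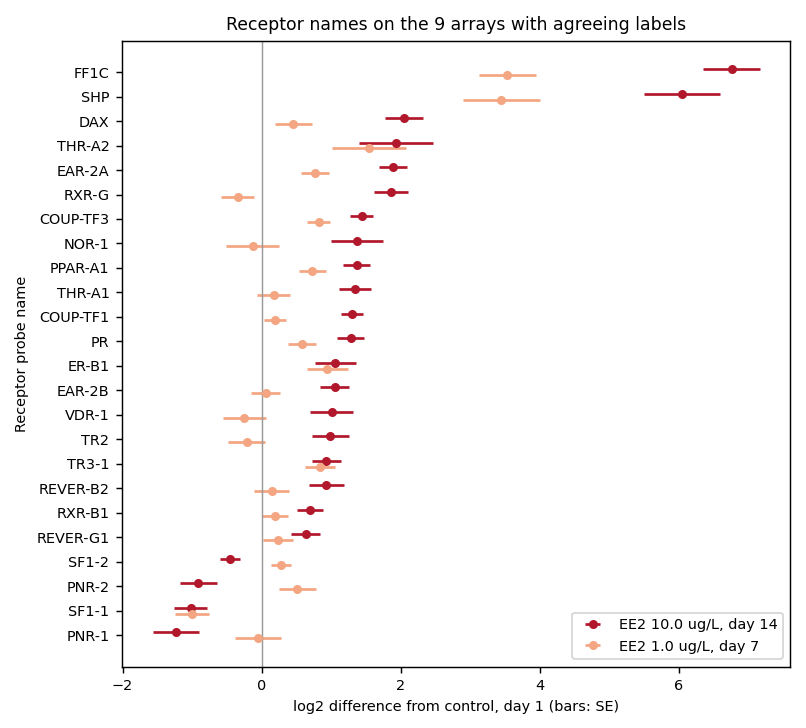
Difference from control testes of day 1 (log2, bars SE, 3 arrays per group) for receptor names that passed in EE2 10.0 µg/L testes of day 14 (red), with the values in EE2 1.0 µg/L testes of day 7 (orange). FF1C and SHP lead in both exposed groups; SHP was not above background in control arrays and PNR-1 on 1 of 3 exposed arrays of day 14, so their points are measured values and not bounds, and SF1-1 and PNR-1 change sign with normexp background correction.

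On day 1, the scanner-file assignment gave few differences from control at either dose. At EE2 1.0 µg/L, 3 probes were higher and 2 lower by limma, and at 10.0 µg/L 0 were higher and 4 lower, while 1217 and 742 probes had an unadjusted p under 0.05. At 1.0 µg/L, ENSORLG00000014421 was 5.99-fold higher and ENSORLG00000012878 7.01-fold lower (limma adjusted p 0.0219 and 0.00971). At 10.0 µg/L, ENSORLG00000012878 was 11.1-fold lower and ENSORLG00000006795 6.67-fold lower (limma adjusted p 0.00434 and 0.0139). No receptor name passed at either dose by limma, over all probes or adjusted over the list alone. ER-A was -0.90 ± 0.44 and -0.39 ± 0.49. The smallest p at 1.0 µg/L were those of COUP-TF3 (0.87 ± 0.30), PPAR-A1 (0.67 ± 0.26) and REVER-G1 (0.70 ± 0.29). At 10.0 µg/L they were those of VDR-1, at least 1.63-fold lower with 0 of 2 exposed arrays above background, TR2 (-0.70 ± 0.30) and REVER-G2 (-1.05 ± 0.47). The count of 5 at 1.0 µg/L moved by over 1.5 times without control of day 1, replicates 2, 3 (2, 3), control of day 14, replicate 1 (24), EE2 1.0 of day 1, replicates 1, 2, 3 (0, 3, 2), EE2 1.0 of day 14, replicate 1 (20) or EE2 10.0 of day 14, replicate 1 (8). That of 4 at 10.0 µg/L did so without control of day 1, replicates 2, 3 (2), control of day 14, replicate 1 (10) or EE2 10.0 of day 1, replicates 2, 3 (0, 2).

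With the value-table assignment, both doses had higher FF1C, SHP and PR on day 1, in the contrasts of scanner-file controls. At EE2 1.0 µg/L, FF1C was higher by 3.95 ± 0.35 (15.4-fold), PR by 1.12 ± 0.18, and SHP at least 4.49-fold higher with 0 of 3 control arrays above background (limma adjusted p 4.23e-06, 0.00292 and 0.006, n = 3 and 3). At 10.0 µg/L, FF1C was higher by 4.46 ± 0.39 (22.1-fold), PR by 1.16 ± 0.20, and SHP at least 13.3-fold higher (limma adjusted p 4.78e-06, 0.00375 and 1.92e-04, n = 2 and 3). PPAR-G changed by -0.99 ± 0.24 (1.34 with normexp) at 10.0 µg/L (limma adjusted p 0.0433). PPAR-G (10.0 µg/L) lost its call without control of day 1, replicates 2, 3 (-0.88, -0.95) or EE2 10.0 of day 1, replicates 2, 3 (-1.10, -0.88), or without any of 8 further arrays that left its value as it was. PR (10.0 µg/L) lost its call without EE2 10.0 of day 1, replicate 3 (1.08). In all, 43 probes were higher and 8 lower at 1.0 µg/L, and 79 higher and 115 lower at 10.0 µg/L (109 and 79 with median scaling, 5685 and 1283 with normexp). These counts moved by over 1.5 times without control of day 1, replicate 3 (33), EE2 1.0 of day 1, replicate 1 (30) or EE2 10.0 of day 14, replicate 1 (79) at 1.0 µg/L. Those of 10.0 µg/L did so without control of day 1, replicates 1, 2, 3 (108, 83, 72), EE2 10.0 of day 1, replicates 2, 3 (93, 48) or EE2 10.0 of day 14, replicate 1 (348). ER-A did not pass (0.07 ± 0.33 and -0.18 ± 0.37).

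On day 7, the scanner-file assignment gave 9 higher and 4 lower probes at EE2 1.0 µg/L (9 and 9 with median scaling), and 968 higher and 583 lower at 10.0 µg/L (776 and 836 with median scaling). The groups of 10.0 µg/L and control shared no slide on day 7, and with the slide as a fixed block 7 probes passed at that dose. Normexp without a block gave 135. There RXR-G was higher in the fit without a block, by 1.39 ± 0.26, TR2 by 1.27 ± 0.27 (-0.11 with the value-table assignment), COUP-TF1 by 1.05 ± 0.29 (-0.06 with the value-table assignment) and PPAR-G by 0.70 ± 0.22 (-0.15 SD with the table values and -0.68 with the value-table assignment) (limma adjusted p 0.00202, 0.00399, 0.0196 and 0.0433, n = 3 and 3). The pregnane X receptor PXR changed by -1.07 ± 0.28 (limma adjusted p 0.0178). No receptor name passed at 1.0 µg/L by limma (1093 probes with unadjusted p under 0.05), where PPAR-G (-0.72 ± 0.22), SF1-1 (-0.86 ± 0.27) and PXR (0.87 ± 0.28) had the smallest p. ER-A did not pass at either dose (-0.90 ± 0.44 and -0.18 ± 0.44). COUP-TF1 (10.0 µg/L) lost its call without control of day 7, replicates 1, 2 (0.93, 1.02) or EE2 10.0 of day 7, replicate 1 (0.89). PPAR-G (10.0 µg/L) lost its call without control of day 7, replicates 1, 3 (0.69, 0.49) or EE2 10.0 of day 7, replicates 1, 2, 3 (0.60, 0.73, 0.76), or without any of 8 further arrays that left its value as it was. PXR (10.0 µg/L) lost its call without control of day 7, replicate 1 (-0.99) or EE2 10.0 of day 7, replicate 2 (-0.95). The counts moved by over 1.5 times without control of day 7, replicates 1, 2, 3 (8, 3, 7), control of day 14, replicate 1 (41), EE2 1.0 of day 7, replicates 1, 3 (7), EE2 1.0 of day 14, replicate 1 (29) or EE2 10.0 of day 14, replicate 1 (29) at 1.0 µg/L. At the higher dose they did so without control of day 7, replicates 1, 2 (956, 813), control of day 14, replicate 1 (2706) or EE2 10.0 of day 7, replicate 1 (743).

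With the value-table assignment, FF1C, SHP and PR were higher at both doses on day 7. At EE2 1.0 µg/L, FF1C was higher by 4.33 ± 0.35 (20.1-fold) and PR by 0.92 ± 0.18, and SHP was at least 4.79-fold higher (limma adjusted p 8.87e-07, 0.0118 and 7.26e-04, n = 3 and 3). At 10.0 µg/L, FF1C was higher by 5.82 ± 0.35 (56.5-fold), PR by 1.22 ± 0.18 and DAX by 1.08 ± 0.24, and SHP was at least 11.1-fold higher (limma adjusted p 5.80e-09, 2.09e-04, 0.0122 and 6.99e-06). SHP was above background on 0 of 3 control arrays. SF1-1 changed by -1.25 ± 0.26 at 10.0 µg/L (limma adjusted p 0.00899). In all, 103 probes were higher and 23 lower at 1.0 µg/L, and 265 higher and 206 lower at 10.0 µg/L. PR (1.0 µg/L) lost its call without control of day 7, replicate 3 (0.83) or EE2 1.0 of day 7, replicate 3 (0.74). DAX (10.0 µg/L) lost its call without control of day 7, replicate 3 (0.94) or EE2 10.0 of day 7, replicate 2 (1.06). SF1-1 (10.0 µg/L) lost its call without EE2 10.0 of day 7, replicate 2 (-0.96). Both counts moved by over 1.5 times when 1 array was left out, that of 1.0 µg/L without control of day 7, replicate 1 (80) or EE2 1.0 of day 7, replicates 2, 3 (73, 69). The count of 10.0 µg/L did so without control of day 7, replicate 1 (269) or EE2 10.0 of day 7, replicate 2 (287). ER-A did not pass (0.08 ± 0.33 and 0.63 ± 0.33).

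**Figure D3:**
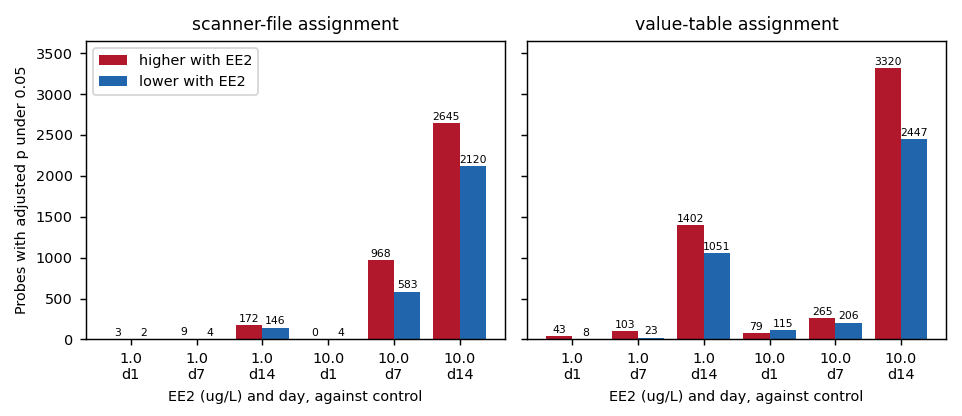
Number of probes (of 12118 tested) with a limma adjusted p under the threshold, higher (red) or lower (blue) than the control of the same day, by EE2 dose and day, for the scanner-file assignment (left) and the value-table assignment (right). EE2 10.0 µg/L on day 14 has the highest counts under both, 2645 higher and 2120 lower on the left and 3320 and 2447 on the right; with median scaling the lower probes outnumber the higher ones in this comparison, and with normexp it does not have the highest counts.

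On day 14, EE2 10.0 µg/L gave the highest counts of exposed against control testes under both assignments, but not with normexp. Normexp gave 5752 probes for 1.0 µg/L and 1333 for 10.0 µg/L on day 14 with scanner-file samples, and 6968 for 10.0 µg/L on day 1 and 1299 on day 14 with value-table samples. With the scanner-file assignment 2645 probes were higher and 2120 lower (1513 and 3767 with median scaling). RXR-G was higher by 2.21 ± 0.26, FF1C by 1.87 ± 0.40 and REVER-B2 by 1.77 ± 0.28 (limma adjusted p 4.76e-06, 9.84e-04 and 5.76e-05, n = 3 and 3). PPAR-G was at least 3.06-fold higher (log2 -0.48 with normexp), the retinoic acid receptor RAR-A at least 1.39-fold (log2 -0.95 with normexp) and THR-B at least 1.64-fold (log2 -0.69 with normexp), each above background on 2 of 3 control arrays (limma adjusted p 1.06e-05, 0.00302 and 0.00762). DAX was higher by 1.07 ± 0.24, RXR-B1 by 0.62 ± 0.24 (-0.002 with normexp) and ER-A by 1.37 ± 0.44 (limma adjusted p 0.0017, 0.0432 and 0.0176). ER-A lost its call without control of day 14, replicate 1 (0.72) or EE2 10.0 of day 14, replicate 1 (1.06). RXR-B1 lost its call without control of day 14, replicate 3 (0.45) or EE2 10.0 of day 14, replicates 1, 2, 3 (0.50, 0.68, 0.68), or without any of 5 further arrays that left its value as it was. THR-B lost its call without EE2 10.0 of day 14, replicate 1. In total, 20 receptor names were higher and 0 lower by limma. At 1.0 µg/L, 172 probes were higher and 146 lower (139 and 155 with median scaling), and SF1-1 was lower (limma adjusted p 0.0429). No size is given for it, as 2 of 3 control arrays were above background. ER-A did not pass at 1.0 µg/L (0.56 ± 0.44). SF1-1 lost its call without any 1 of 14 of the 26 arrays. The count of 318 at 1.0 µg/L moved by over 1.5 times without control of day 14, replicates 1, 2, 3 (164, 2609, 2031) or EE2 1.0 of day 14, replicates 2, 3 (120, 139). No array moved the count at 10.0 µg/L by as much.

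Under the value-table assignment, EE2 10.0 µg/L on day 14 had FF1C higher by 7.50 ± 0.39 (181-fold), RXR-G by 2.32 ± 0.24, EAR-2A by 2.18 ± 0.47 (-0.03 with normexp) and DAX by 2.10 ± 0.27 (limma adjusted p 3.19e-10, 1.63e-06, 9.44e-04 and 9.88e-06, n = 3 and 2). THR-A1, THR-A2, TR3-1, RAR-A and RXR-B1 were higher by 1.90 ± 0.33 (-0.17 with normexp), 1.86 ± 0.44 (-0.31 with normexp), 1.18 ± 0.25, 1.06 ± 0.25 (-0.47 with normexp) and 0.93 ± 0.26. SHP was at least 30.9-fold higher with 0 of 2 control arrays above background (limma adjusted p 6.78e-08). ER-A was higher by 0.92 ± 0.37 (limma adjusted p 0.0469). SF1-1 and SF1-2 changed by -0.92 ± 0.30 and -0.75 ± 0.19, and PNR-1 was at least 2.17-fold lower, above background on 1 of 3 against 2 of 2 arrays (limma adjusted p 0.0168, 0.00351 and 0.0126). At 1.0 µg/L, FF1C was higher by 5.73 ± 0.39 (53-fold), DAX by 1.65 ± 0.27, RXR-G by 1.61 ± 0.24 and PR by 1.23 ± 0.20, and SHP was at least 6.11-fold higher (log2 -0.45 with normexp) (limma adjusted p 2.91e-08, 4.37e-04, 2.58e-04, 4.50e-04 and 2.43e-05). PXR, ERR-A, REVER-G1 and SF1-2 changed there by -1.11 ± 0.28, -1.06 ± 0.33, -1.02 ± 0.32 and -0.76 ± 0.19, RAR-A by 0.73 ± 0.25 (-0.95 with normexp), and ER-A did not pass (0.28 ± 0.37). ERR-A (1.0 µg/L) lost its call without control of day 14, replicates 2, 3 (-0.85, -1.28) or EE2 1.0 of day 14, replicates 1, 2 (-0.97, -1.02). PXR (1.0 µg/L) lost its call without control of day 14, replicate 2 (-1.01). RAR-A (1.0 µg/L) lost its call without any 1 of 18 of the 25 arrays (0.36 to 0.78). REVER-G1 (1.0 µg/L) lost its call without control of day 14, replicate 3 (-0.62) or EE2 1.0 of day 14, replicates 1, 2 (-1.07, -0.91). SF1-2 (1.0 µg/L) lost its call without control of day 14, replicate 2 (-0.67). ER-A (10.0 µg/L) lost its call without control of day 14, replicates 2, 3 (1.06, 0.79) or EE2 10.0 of day 14, replicate 1 (0.61), or without any of 10 further arrays that left its value as it was. PNR-1 (10.0 µg/L) lost its call without control of day 14, replicate 2 or EE2 10.0 of day 14, replicate 1. RAR-A (10.0 µg/L) lost its call without control of day 14, replicate 2 (0.69). RXR-B1 (10.0 µg/L) lost its call without control of day 14, replicate 3 (0.76). SF1-1 (10.0 µg/L) lost its call without control of day 14, replicate 3 (-0.78) or EE2 10.0 of day 14, replicate 2 (-0.76). In total, 3320 probes were higher and 2447 lower at 10.0 µg/L (2153 and 4064 with median scaling, 554 and 745 with normexp), and 1402 higher and 1051 lower at 1.0 µg/L (1046 and 1928 with median scaling, 128 and 62 with normexp). The count at 1.0 µg/L moved by over 1.5 times without control of day 14, replicates 2, 3 (877, 1277) or EE2 1.0 of day 14, replicate 1 (1345).

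**Figure D4:**
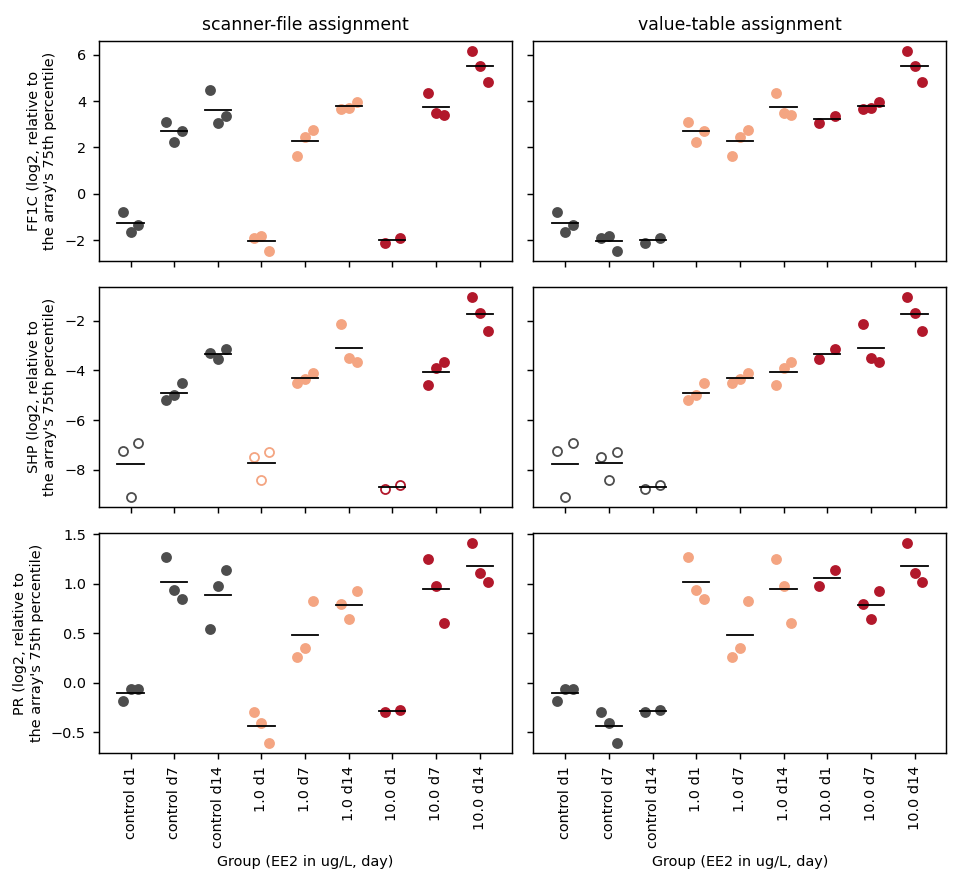
Level of FF1C, SHP and PR on each array (log2 relative to the 75th percentile of the array), by group, with the scanner-file assignment (left, 26 arrays) and the value-table assignment (right, 25 arrays). Grey is control, orange EE2 1.0 µg/L and red 10.0 µg/L, open circles were not well above background and lines are group means; SHP is open in all day 1 groups on the left and in all control groups on the right.

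Direct comparison of the doses also differed between the assignments. With the scanner-file assignment, EE2 10.0 against 1.0 µg/L gave 0 higher and 19 lower probes on day 1 by limma (1080 with unadjusted p under 0.05), 1077 and 1198 on day 7 (851 and 1414 with median scaling), and 3080 and 1966 on day 14 (1866 and 2909 with median scaling). No receptor name passed on day 1 (0 higher and 2 lower adjusted over the list alone), where COUP-TF3, TLX and THR-A1 had the smallest p (-1.46 ± 0.34, -1.66 ± 0.42 and -1.06 ± 0.34). On day 7, RXR-G and FF1C were higher by 1.5 ± 0.26 and 1.45 ± 0.40, and PXR, REVER-G1 and SF1-2 changed by -1.94 ± 0.28, -1.01 ± 0.29 (0.11 SD with the table values and 0.31 with the value-table assignment) and -0.74 ± 0.24 (0.10 SD with the table values and 0.38 with the value-table assignment) (limma adjusted p 0.00151, 0.0158, 8.04e-04, 0.0189 and 0.0346). On day 14, RXR-G and EAR-2A were higher by 1.97 ± 0.26 and 1.85 ± 0.41, and SF1-2 changed by -1.11 ± 0.24 (0.005 SD with the table values and 0.008 with the value-table assignment) (limma adjusted p 2.38e-05, 0.0015 and 0.00113). PNR-1 was at least 1.85-fold lower, above background on 1 of 3 against 3 of 3 arrays (log2 0.19 with normexp) (limma adjusted p 0.0349). LRH-1 passed as well (adjusted p 0.00635), but only replicate 3 of EE2 10.0 µg/L was above background, so no size is given. COUP-TF3 (day 1) was called without control of day 14, replicates 1, 2 (-1.46) or EE2 1.0 of day 14, replicates 1, 2 (-1.46). TLX (day 1) was called without control of day 14, replicate 1 (-1.66). FF1C (day 7) lost its call without EE2 1.0 of day 7, replicate 1 (1.13) or EE2 10.0 of day 7, replicate 1 (1.15). REVER-G1 (day 7) lost its call without EE2 1.0 of day 7, replicates 1, 2 (-0.91, -0.90) or EE2 10.0 of day 7, replicate 2 (-0.91). SF1-2 (day 7) lost its call without EE2 1.0 of day 7, replicates 1, 2, 3 (-0.69, -0.80, -0.71) or EE2 10.0 of day 7, replicates 1, 3 (-0.66, -0.70). PNR-1 (day 14) lost its call without EE2 1.0 of day 14, replicates 1, 2 or EE2 10.0 of day 14, replicates 1, 3. With the value-table assignment, 0 probes passed on day 1 by limma (689 with unadjusted p under 0.05, the smallest p among the names in COUP-TF1, ROR-A2 and SHP with -0.79 ± 0.23, -1.04 ± 0.34 and 1.57 ± 0.56), 46 were higher and 53 lower on day 7 (66 and 52 with median scaling), and 1127 higher and 604 lower on day 14 (785 and 1215 with median scaling). There, SHP, THR-A1 and FF1C were higher by 2.34 ± 0.50, 1.79 ± 0.29 and 1.77 ± 0.35 on day 14, and ROR-A2 changed by -1.34 ± 0.30 on day 7. ROR-A2 (day 7) lost its call without EE2 1.0 of day 7, replicates 1, 2, 3 (-1.25, -1.27, -1.49) or EE2 10.0 of day 7, replicates 1, 2 (-1.24, -1.20), or without any of 8 further arrays that left its value as it was. Scanner-file counts moved by over 1.5 times without control of day 7, replicate 1 (7), control of day 14, replicates 1, 2 (31, 46), EE2 1.0 of day 1, replicates 1, 2, 3 (3, 12, 6), EE2 1.0 of day 7, replicate 3 (50), EE2 1.0 of day 14, replicates 1, 3 (127, 29) or EE2 10.0 of day 1, replicates 2, 3 (6, 1) on day 1. They did so on day 7 without control of day 14, replicate 1 (3614), EE2 1.0 of day 7, replicates 1, 2 (1263, 1401) or EE2 10.0 of day 7, replicate 1 (1030). Day 14 counts did so without EE2 10.0 of day 14, replicate 1 (3360). Value-table counts did so on day 1 without EE2 10.0 of day 7, replicate 1 (1). Day 7 counts of that assignment did so without control of day 1, replicate 3 (62), EE2 1.0 of day 7, replicates 1, 2 (37, 24), EE2 10.0 of day 7, replicates 1, 2 (215, 14) or EE2 10.0 of day 14, replicate 1 (190). Those of day 14 did so without EE2 1.0 of day 14, replicates 2, 3 (933, 1008) or EE2 10.0 of day 14, replicate 1 (666).

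The EE2 effect on day 14 was tested against that on day 1 as an interaction. With the scanner-file assignment the effect of 1.0 µg/L differed at 62 probes higher and 55 lower (70 and 135 with median scaling), and that of 10.0 µg/L at 1904 and 1146 (896 and 2507 with median scaling). For 10.0 µg/L the effects differed by 2.67 ± 0.40 (-0.17 with normexp) in RXR-G and 2.61 ± 0.59 in FF1C (limma adjusted p 1.99e-04 and 0.00377). SHP passed too (adjusted p 0.0156), but was below background on every array of day 1 in that test, so the size of its difference was not measured. SHP lost its call without EE2 10.0 of day 1, replicate 2. For 1.0 µg/L no receptor name passed, with the smallest p in PPAR-A1 and COUP-TF3 (-1.42 ± 0.36 and -1.66 ± 0.43), while 1 higher and 2 lower passed when adjusted over the list alone. COUP-TF3 was called without control of day 14, replicate 2 (-2.07) or EE2 1.0 of day 14, replicate 1 (-1.97). PPAR-A1 was called without control of day 14, replicates 2, 3 (-1.71, -1.49), EE2 1.0 of day 14, replicate 1 (-1.59) or EE2 10.0 of day 14, replicate 1 (-1.42). With the value-table assignment the effect of 1.0 µg/L differed at 734 probes higher and 342 lower (504 and 801 with median scaling), and that of 10.0 µg/L at 2387 and 1522 (1312 and 2878 with median scaling). The 10.0 µg/L test is the same contrast under both assignments, since exchanging dose and day leaves it unchanged. It differs only by the low-signal array, without which the scanner-file count was also 3909, so it is not a second result. Without that array, effects of 10.0 µg/L differed by 3.04 ± 0.56 in FF1C, 2.99 ± 0.35 (-0.17 with normexp) in RXR-G, -1.33 ± 0.47 in ERR-A and -1.14 ± 0.27 in SF1-2. SHP passed as well, with no size measured, as it was below background on every control array. Those of 1.0 µg/L differed by 1.97 ± 0.35 (-0.74 with normexp) in TR2, 1.85 ± 0.33 in RXR-G and -0.88 ± 0.26 in SF1-2. SF1-2 (1.0 µg/L) lost its call without control of day 1, replicates 1, 2, 3 (-0.90, -0.89, -0.86), EE2 1.0 of day 1, replicates 1, 2 (-0.80, -0.76), control of day 14, replicates 2, 3 (-0.79, -0.98) or EE2 1.0 of day 14, replicates 1, 3 (-0.80, -0.84). ERR-A (10.0 µg/L) lost its call without control of day 1, replicates 1, 2, 3 (-1.28, -1.35, -1.36), EE2 10.0 of day 1, replicate 2 (-1.12), control of day 14, replicate 2 (-1.12) or EE2 10.0 of day 14, replicates 1, 2 (-1.01, -1.15). SHP (10.0 µg/L) lost its call without control of day 1, replicate 3, EE2 10.0 of day 1, replicate 2, control of day 14, replicate 2 or EE2 10.0 of day 14, replicate 1. The scanner-file count of 1.0 µg/L moved by over 1.5 times without control of day 1, replicates 1, 2, 3 (71, 24, 48), control of day 14, replicates 1, 2, 3 (58, 1689, 340), EE2 1.0 of day 1, replicates 1, 3 (29, 55), EE2 1.0 of day 7, replicate 2 (64), EE2 1.0 of day 14, replicates 1, 2, 3 (429, 30, 41), EE2 10.0 of day 7, replicates 2, 3 (72, 71) or EE2 10.0 of day 14, replicate 1 (177). That of 10.0 µg/L did so without EE2 10.0 of day 1, replicate 2 (1870). The value-table count of 1.0 µg/L did so without control of day 1, replicates 1, 2 (583, 667), EE2 1.0 of day 1, replicates 1, 2 (707, 606), control of day 14, replicates 2, 3 (238, 581) or EE2 1.0 of day 14, replicate 1 (509).

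Averaged over the 3 days, EE2 10.0 µg/L gave 1687 higher and 1517 lower probes with the scanner-file assignment (1222 and 2385 with median scaling), and EE2 1.0 µg/L 133 and 114 (109 and 132 with median scaling). With the slide as a fixed block 4 probes remained for 1.0 µg/L, and normexp without a block gave 49 there and 548 for 10.0 µg/L. RXR-G and COUP-TF1 were higher by 1.04 ± 0.16 and 0.92 ± 0.17 at 10.0 µg/L, and ER-B2 changed by -0.86 ± 0.22 (0.06 SD with the table values and 0.23 with the value-table assignment) at 1.0 µg/L (limma adjusted p 0.0413). SF1-1 was lower at 1.0 µg/L (limma adjusted p 0.0101), with no size given, since 1 control array of day 14 was not above background. ER-B2 lost its call without any 1 of 17 of the 26 arrays (-0.90 to -0.77). Value-table means gave 1384 higher and 1206 lower at 10.0 µg/L (1118 and 2115 with median scaling) and 534 and 208 at 1.0 µg/L (486 and 314 with median scaling). FF1C was higher by 4.67 ± 0.21 at 1.0 µg/L and by 5.93 ± 0.22 at 10.0 µg/L. SHP was higher at both doses, by an amount not measured, since it was below background on every control array. SF1-1 changed by -0.90 ± 0.17 (0.14 with normexp) at 10.0 µg/L. LRH-1 passed there but lay below background on some or all arrays of each exposed group, so no size is given (its sign changed with normexp). LRH-1 lost its call without any 1 of 24 of the 25 arrays. Left out in turn, 1 array moved the scanner-file count of 1.0 µg/L by over 1.5 times, without control of day 1, replicate 2 (161) or control of day 14, replicate 1 (494). The value-table count of 10.0 µg/L did so without EE2 10.0 of day 1, replicate 3 (1707).

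Vehicle controls of days 7 and 14 were compared with those of day 1. With scanner-file labels, those of day 7 differed at 33 higher and 7 lower probes, and controls of day 14 at 512 and 578 (755 and 363 with median scaling). FF1C was higher by 3.95 ± 0.40 (-0.23 SD with the table values and -0.79 with the value-table assignment) on day 7 and by 4.89 ± 0.40 (-0.11 SD with the table values and -0.74 with the value-table assignment) on day 14. SHP was at least 4.49-fold (-0.06 SD with the table values) and at least 13.4-fold (-0.24 SD with the table values and log2 -0.93 with the value-table assignment) higher with 0 of 3 arrays of day 1 above background. PR was higher by 1.12 ± 0.20 (-0.10 SD with the table values and -0.34 with the value-table assignment) on day 7, and PPAR-A1 by 1.04 ± 0.26 on day 14 (limma adjusted p 0.0078 and 0.0217). On day 14 PPAR-G was at least 1.94-fold lower, above background on 2 of 3 against 3 of 3 arrays (log2 1.28 with normexp), and LXR changed by -0.64 ± 0.19 (0.30 with normexp). PR (day 7) lost its call without control of day 1, replicate 1 (1.08) or control of day 7, replicate 1 (0.99). LXR (day 14) lost its call without control of day 1, replicates 1, 2, 3 (-0.66, -0.58, -0.70) or control of day 14, replicate 1 (-0.36), or without any of 10 further arrays that left its value as it was. PPAR-A1 (day 14) lost its call without control of day 1, replicates 1, 2, 3 (1.1, 1.04, 0.98) or control of day 14, replicate 1 (0.68). PPAR-G (day 14) lost its call without control of day 1, replicates 2, 3. With value-table labels 17 probes were higher and 7 lower on day 7, and 1 higher and 9 lower on day 14, and no receptor name passed by limma (2090 and 1197 probes with unadjusted p under 0.05). FF1C, chosen here after its values were seen, was -0.79 ± 0.35 on day 7 and -0.74 ± 0.39 on day 14. The smallest p were those of COUP-TF3, PPAR-A1 and TLX on day 7 (0.87 ± 0.26, 0.67 ± 0.19 and 0.84 ± 0.31) and on day 14 those of VDR-1 (at least 1.63-fold lower, above background on 0 of 2 against 3 of 3 arrays), TR2 (-0.70 ± 0.26) and TLX (-0.82 ± 0.34). Scanner-file counts moved by over 1.5 times on day 7 without control of day 7, replicate 1 (22). On day 14 they did so without control of day 1, replicates 1, 2, 3 (315, 170, 166) or control of day 14, replicates 1, 2, 3 (194, 3164, 2499). Value-table counts did so on day 7 without control of day 1, replicates 1, 2, 3 (7, 4, 5), EE2 1.0 of day 1, replicate 1 (9), control of day 7, replicates 1, 2, 3 (5, 4, 85), EE2 1.0 of day 7, replicate 2 (6), EE2 10.0 of day 7, replicates 1, 3 (91, 8), control of day 14, replicates 2, 3 (9), EE2 1.0 of day 14, replicates 1, 2, 3 (12, 13, 8) or EE2 10.0 of day 14, replicate 1 (45). For day 14 this held without control of day 1, replicate 2 (3), control of day 14, replicates 2, 3 (3, 2) or EE2 10.0 of day 14, replicate 1 (16).

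Normexp background correction changed the counts of the value-table assignment. It gave 12, 24 and 190 probes at 1.0 µg/L on days 1, 7 and 14, 6968, 104 and 1299 at 10.0 µg/L, and 0 (7140 with unadjusted p under 0.05), 3 and 16 between doses. The effects of day 14 against day 1 came to 7 and 6240 for 1.0 and 10.0 µg/L, the means over days to 94 and 600, and the controls of days 7 and 14 against day 1 to 0 (403 with unadjusted p under 0.05) and 0 (3767 with unadjusted p under 0.05). The cause was not tested.

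In the value-table assignment 29 probes were higher and 1 lower in all 6 comparisons of exposed with control testes, FF1C, SHP and PR among them, against 1.65e-06 and 4.29e-08 expected from independent lists. The scanner-file assignment had 0 such probes each way by limma, with 742 to 5804 probes per comparison at an unadjusted p under 0.05. On day 14, the doses shared 1329 higher and 939 lower probes (384 and 212 expected from independent lists) in the value-table assignment, and 126 and 61 (37.5 and 25.5 expected) in the scanner-file assignment. Unchanged groups simulated against the same controls shared 0 probes (20 simulations), where few can pass, so the excess stays untested. The controls were too few to split, so part of it may come from sharing them.

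Of 22 gene lists fixed beforehand, the hormone receptor list had enough tested genes for a set test (16 genes). With the scanner-file assignment it did not pass in any of the 6 comparisons of exposed with control testes (camera adjusted p 0.235 to 0.989). At 10.0 µg/L on day 14 its median was 0.45 against 0.09 for all probes, with 5 genes higher and 0 lower (5 and 0 adjusted over the list alone). There fry, which tests whether the genes move one way on balance, gave an adjusted p of 7.79e-05. With the value-table assignment the list was higher by camera at 1.0 µg/L on days 1, 7 and 14 (adjusted p 0.00944, 1.24e-04 and 0.0384) and at 10.0 µg/L on days 7 and 14 (0.00979 and 0.00944), and did not pass at 10.0 µg/L on day 1 (0.0973). With an estimated correlation between genes, the call at 1.0 µg/L on day 7 held (adjusted p 0.0229) and the other 4 did not (0.0696 to 0.13).

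The 26 arrays lay on 5 slides (8, 7, 7, 3 and 1 arrays). Scanner-file samples had 1 comparison of exposed with control testes with both groups on a slide, EE2 1.0 µg/L on day 14. That slide held 1 exposed and 1 control array, between which FF1C differed by 0.29, a value with no test. Value-table samples shared a slide in 5 such comparisons. Within slides 21, 17 and 2063 probes passed at 1.0 µg/L on days 1, 7 and 14. FF1C was higher there by 3.95, 4.09 and 5.73. For EE2 10.0 µg/L on days 1 and 7 the slide held 1 exposed array, in which FF1C was higher by 4.30 and 5.72, also without a test. These fits hold fewer arrays than those of all slides, so their counts were not set against them. A fixed slide block in the fit of all arrays left 14, 7 and 4 scanner-file probes for 1.0 µg/L on day 14, 10.0 µg/L on day 7 and the doses of day 7. With value-table samples it left 44, 49 and 2311 at 1.0 µg/L on days 1, 7 and 14 and 45 and 174 at 10.0 µg/L on days 1 and 7. The other comparisons with control, and all those of the agreeing arrays, had no slide with both groups, so slide and group could not be told apart without a model of the slides.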

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

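The tests of the slide, of a single exposed array, of the low-signal control array and of the wrong files or wrong column order were chosen only after the result was seen, and the splits of the arrays were fixed before their counts were seen.

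The effect of EE2 was found to differ between day 14 and day 1 by a limma test of the difference itself. With the scanner-file assignment this concerned 117 probes at 1.0 µg/L and 3050 at 10.0 µg/L, where the difference of log2 effects was 2.67 in RXR-G, 2.61 in FF1C and nominally 2.54 in SHP. Under the value-table assignment it concerned 1076 probes at 1.0 µg/L, with 1.97 in TR2, 1.85 in RXR-G and -0.88 in SF1-2. The test of the higher dose is the same contrast under both assignments. Without the low-signal array, which is the only difference, it concerned 3909 probes, with 3.04 in FF1C, 2.99 in RXR-G, nominally 2.54 in SHP, -1.33 in ERR-A and -1.14 in SF1-2. The values of SHP do not measure a size, since it was below background on all arrays of 2 of the 4 groups in the contrast. Of these, RXR-G and SHP at 10.0 µg/L (with and without the low-signal array) and TR2 at 1.0 µg/L (value-table assignment) had the opposite sign with normexp background correction.

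The value-table column of the control of day 14, replicate 1, matched no scanner file and entered only the alternative with the table values. FF1C stood at 0.479 there (deposited score, in SD of the column), above the 0.252 and 0.315 of the other columns of that control group. In the scanner file of the same sample, brought to the same scale, FF1C stood at 1.94. SHP and PR ran the other way in that column, at -1.51 and 0.703, below the lowest of the other columns (-1.46 and 0.718).

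Counts of comparisons with at least 3 arrays in each group, and of the means over days, were also taken over other splits of the same arrays into groups of the same sizes. Groups of 3 and 3 arrays make 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave a count as large. With the scanner-file assignment the real counts and the highest of the other splits were 5 against 1, 13 against 0 and 318 against 142 for 1.0 µg/L on days 1, 7 and 14. They were 1551 against 1 and 4765 against 1693 for 10.0 µg/L on days 7 and 14, 2275 against 0 and 5046 against 4 between doses on days 7 and 14. Controls gave 40 against 1 and 1090 against 1 on days 7 and 14 against day 1. The agreeing arrays gave 128 against 0, 5176 against 0 and 5019 against 0 for 1.0 µg/L, 10.0 µg/L and the difference between doses. Value-table samples gave 51 against 1, 126 against 1 and 471 against 2 for 1.0 µg/L on days 1 and 7 and 10.0 µg/L on day 7. They gave 99 against 86, 1731 against 553 and 24 against 2 for the doses of days 7 and 14 and the controls of day 7 against day 1.

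For the means over days, the share of splits with a count as large as the real one was under 0.05. With the scanner-file assignment it was 1 of 100 splits at 1.0 µg/L (247 against 174) and 1 at 10.0 µg/L (3204 against 3127). This does not exclude the slide, since with it as a fixed block 4 probes remained at 1.0 µg/L. Value-table splits as large were 1 (742 against 545) and 2 (2590 against 2869), each number of splits including the real one. For the 1.0 µg/L effect of day 14 against day 1, 2 of 100 splits gave as many as the real 117 probes, so that chance can be excluded at that share. The highest other split called 459, several times the real count, which points to a structure of the samples other than the groups, and leaving out 1 array moved the real count between 24 and 1689. What that structure is was not tested.

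The first pattern was that 16 of the 26 value-table columns held the array that the scanner files give to another sample. That the scanner files were attached to the wrong samples stays open: with the value table's labels the controls of days 14 and 1 differed at 10 probes, but these arrays are all of day 1 by the scanner files as well. That the columns of the table were put in the wrong order also stays open: 25 columns held a scanner file found in no other column, which wrong files would give too. These explanations cannot be told apart, and no biological explanation applies to a label.

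A second pattern was the large number of probes at which EE2 10.0 µg/L on day 14 differed from control. It does not rest on 1 of the 3 exposed arrays, since without any 1 of them at least 3256 probes passed, of 4765. The slide that held only these 3 arrays cannot be told apart from the exposure, as the groups compared share no slide; the within-slide correlation over the other arrays was -0.02 and decides nothing for them. An effect of EE2 itself stays open and was not tested apart from the slide.

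The third pattern was that counts against the control of day 14 moved when 1 of its 3 arrays was left out. Of the pairs of arrays that remain, the pair without the array of lowest signal (replicate 1) gave 164 probes at 1.0 µg/L on day 14, and the 2 pairs with it 2609 and 2031, of 318 with all 3. For the control of day 14 against day 1 these counts were 194 against 3164 and 2499, and for the 1.0 µg/L effect over time 58 against 1689 and 340. The high counts thus went with the array of lowest signal. For 10.0 µg/L on day 14 the count was instead higher without it (5352, of 4765 with all 3). That array also stood apart from the other 2 controls of day 14 on the second principal component (121, against 2.86 and 12.9) and had 8423 probes well above background, against 11101 and 11517. The test was set after these counts were seen, so the array as their cause stays open. Weak hybridisation and a difference of the fish in that beaker both stay open, since they rest on the same array.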

How the results depend on the processing

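The value-table assignment, the comparisons of the agreeing arrays and every alternative applied to either were chosen after the result was seen, and all other alternatives were fixed before. Among alternatives other than leaving out 1 array, counts of the scanner-file assignment stayed within 1.5 times of the reported count in 104 cases and left that range in 87. For the agreeing arrays these were 27 and 6. For the value-table assignment they were 110 and 51. Named receptors and the receptor list kept direction and side of the threshold in 778 cases of the scanner-file assignment, lost the call in 115, gained one in 24 and changed sign or direction in 32. For the agreeing arrays the cases were 339, 17, 1 and 4, and for the value-table assignment 878, 94, 2 and 14. Beside each limma count of 0 stands the count at an unadjusted p under 0.05 (unadjusted). Where no cause is named below, the cause was not tested. The reported counts against control were 5, 13 and 318 at 1.0 µg/L on days 1, 7 and 14 and 4, 1551 and 4765 at 10.0 µg/L, and 19, 2275 and 5046 between doses. The effects of day 14 against day 1 gave 117 and 3050, the means over days 247 and 3204, the controls 40 and 1090 and the agreeing arrays 128, 5176 and 5019.

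Normexp background correction in place of the processed signal gave 0 (261 unadjusted), 0 (207 unadjusted) and 5752 (602 higher, 5150 lower) at 1.0 µg/L on days 1, 7 and 14. Normexp gave 0 (3845 unadjusted), 135 (111 higher, 24 lower) and 1333 (533 higher, 800 lower) at 10.0 µg/L on days 1, 7 and 14. It gave 0 (674 unadjusted), 193 and 1577 (712 higher, 865 lower) between doses on days 1, 7 and 14. Then it gave 9 for the 1.0 µg/L effect of day 14 against day 1, 5474 (478 higher, 4996 lower) for that of 10.0 µg/L and 49 for the mean of 1.0 µg/L over days. It also gave 548 (360 higher, 188 lower) for the mean of 10.0 µg/L over days, 10 (10 higher, 0 lower) between controls of days 7 and 1 and 6277 (5716 higher, 561 lower) between controls of days 14 and 1. Normexp gave 81 for the agreeing arrays of 1.0 µg/L and 6940 (5232 higher, 1708 lower) for the agreeing arrays of 10.0 µg/L. Signs changed to PPAR-G, RAR-A, THR-B and RXR-B1 -0.48, -0.95, -0.69 and -0.002 (10.0 µg/L of day 14), PNR-1 0.19 (doses of day 14) and RXR-G and SHP -0.17 and -1.61 (10.0 µg/L effect over time). Further changes were PPAR-G and LXR 1.28 and 0.30 (controls of days 1 and 14), PNR-1 and SF1-1 0.50 and 0.25 (agreeing arrays, 10.0 µg/L) and TR3-2 and PNR-1 0.22 and 0.14 (agreeing arrays, doses). Value-table signs changed with normexp to SHP and RAR-A -0.45 and -0.95 (1.0 µg/L of day 14), PPAR-G 1.34 (10.0 µg/L of day 1) and EAR-2A, THR-A1, THR-A2 and RAR-A -0.029, -0.17, -0.31 and -0.47 (10.0 µg/L of day 14). Further changes were TR2 -0.74 (1.0 µg/L effect over time), RXR-G and SHP -0.17 and -1.65 (10.0 µg/L effect over time) and LRH-1 and SF1-1 0.36 and 0.14 (mean of 10.0 µg/L). The median of all tested probes ranged over the comparisons from -1.02 to 0.76 with normexp, against -0.08 to 0.17 as reported.

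Scaling by the median gave 9 between doses on day 1. Median scaling gave 205 (70 higher, 135 lower) for the 1.0 µg/L effect of day 14 against day 1 and 197 for the agreeing arrays of 1.0 µg/L. Other splits stand in the report where the share of higher probes moved by over 10 points or the larger side changed. The median of all tested probes then ranged from -0.38 to 0.18. Quantile normalization gave 11 (5 higher, 6 lower) and 19 (9 higher, 10 lower) at 1.0 µg/L on days 1 and 7. Quantile scaling gave 2 and 5236 (2501 higher, 2735 lower) between doses on days 1 and 14. It gave 2720 (1353 higher, 1367 lower) for the 10.0 µg/L effect of day 14 against day 1, 5323 (2216 higher, 3107 lower) for the agreeing arrays of 10.0 µg/L and 5062 (2264 higher, 2798 lower) between doses of the agreeing arrays. Its medians of all tested probes ranged from -0.15 to 0.06. The reported directions of these counts were therefore relative to the 75th percentile of each array.

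The deposited values of the value table, taken by their column headers, gave 52 (43 higher, 9 lower), 133 (109 higher, 24 lower) and 3011 at 1.0 µg/L on days 1, 7 and 14. The table gave 349 (123 higher, 226 lower), 493 and 6565 (2826 higher, 3739 lower) at 10.0 µg/L on days 1, 7 and 14. It gave 0 (851 unadjusted), 78 (49 higher, 29 lower) and 2293 (1018 higher, 1275 lower) between doses on days 1, 7 and 14. Then it gave 1036 for the 1.0 µg/L effect of day 14 against day 1, 4048 (1938 higher, 2110 lower) for that of 10.0 µg/L and 836 (550 higher, 286 lower) for the mean of 1.0 µg/L over days. It also gave 3304 (1285 higher, 2019 lower) for the mean of 10.0 µg/L over days, 77 (28 higher, 49 lower) between controls of days 7 and 1 and 9 (1 higher, 8 lower) between controls of days 14 and 1. The table gave 102 (70 higher, 32 lower) for the agreeing arrays of 1.0 µg/L and 5499 (2218 higher, 3281 lower) for the agreeing arrays of 10.0 µg/L. Signs changed to (in SD of a column) PPAR-G -0.15 (10.0 µg/L of day 7), REVER-G1 and SF1-2 0.11 and 0.098 (doses of day 7) and SF1-2 0.005 (doses of day 14). Further changes were ER-B2 0.064 (mean of 1.0 µg/L), FF1C, SHP and PR -0.23, -0.065 and -0.10 (controls of days 1 and 7) and FF1C and SHP -0.11 and -0.24 (controls of days 1 and 14). The value-table assignment of the scanner files gave 51, 126 and 2453 at 1.0 µg/L on days 1, 7 and 14. This assignment gave 194 and 471 at 10.0 µg/L on days 1 and 7. It gave 0 (689 unadjusted), 99 and 1731 between doses on days 1, 7 and 14. Then it gave 1076 for the 1.0 µg/L effect of day 14 against day 1, 742 for the mean of 1.0 µg/L over days and 24 between controls of days 7 and 1. It also gave 10 between controls of days 14 and 1. Signs changed there to TR2, COUP-TF1 and PPAR-G -0.11, -0.058 and -0.68 (10.0 µg/L of day 7), REVER-G1 and SF1-2 0.31 and 0.38 (doses of day 7) and SF1-2 0.008 (doses of day 14). Further changes were ER-B2 0.23 (mean of 1.0 µg/L), FF1C and PR -0.79 and -0.34 (controls of days 1 and 7) and FF1C and SHP -0.74 and -0.93 (controls of days 1 and 14). By construction both alternatives follow the column headers, which place 16 arrays in another group. The hormone receptor list reversed its direction for 1.0 µg/L of day 1, to adjusted p 0.0154 with the table values and 0.00944 with the value-table assignment (camera in limma).

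Array weights gave 128, 1023 and 625 at 1.0 µg/L on days 1, 7 and 14. Weighting gave 66 and 4161 at 10.0 µg/L on days 1 and 7. It gave 120 and 5076 between doses on days 1 and 7. Then it gave 695 for the 1.0 µg/L effect of day 14 against day 1, 1442 for the mean of 1.0 µg/L over days and 4987 for the mean of 10.0 µg/L over days. It also gave 225 between controls of days 7 and 1 and 1812 for the agreeing arrays of 1.0 µg/L. A trended and robust variance gave 11 between doses on day 1. Testing the dim probes too gave 205 for the 1.0 µg/L effect of day 14 against day 1 and 2603 between controls of days 14 and 1. The probes above background on all arrays, fewer by construction, gave 5 at 1.0 µg/L on day 7. This filter gave 1 between doses on day 1. It gave 57 for the 1.0 µg/L effect of day 14 against day 1 and 20 between controls of days 7 and 1. Fitting only the arrays of the groups compared, which leaves fewer arrays for the spread, gave 66, 1 and 1 at 1.0 µg/L on days 1, 7 and 14. Fitting so gave 0 (1725 unadjusted) and 1152 at 10.0 µg/L on days 1 and 14. It gave 109 between doses on day 1. Then it gave 25 for the 1.0 µg/L effect of day 14 against day 1, 1167 for that of 10.0 µg/L and 21 between controls of days 7 and 1. It also gave 23 between controls of days 14 and 1 and 477 for the agreeing arrays of 1.0 µg/L.

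The slide as a fixed block gave 1, 1 and 14 at 1.0 µg/L on days 1, 7 and 14. The fixed block gave 1 and 7 at 10.0 µg/L on days 1 and 7. It gave 6 and 4 between doses on days 1 and 7. Then it gave 11 for the 1.0 µg/L effect of day 14 against day 1, 4 for the mean of 1.0 µg/L over days and 2158 between controls of days 14 and 1. The fixed block could not be estimated for 10.0 µg/L of day 14 against control, for the doses of day 14, for the 10.0 µg/L effect over time, for the mean of 10.0 µg/L or for the agreeing arrays, since 1 slide held all EE2 10.0 µg/L arrays of day 14 and no others (for the agreeing arrays of 1.0 µg/L, since those of the control lay on a slide of their own). The slide as a random block gave 39 between doses on day 1. The random block gave 177 for the 1.0 µg/L effect of day 14 against day 1, 415 for the mean of 1.0 µg/L over days and 734 for the agreeing arrays of 1.0 µg/L. The value-table assignment changes nothing on the agreeing arrays and has no value there.

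A replicate block (the replicate number of the labels, as if paired) gave 501 at 1.0 µg/L on day 14. Pairing gave 10 between doses on day 1. It gave 278 for the 1.0 µg/L effect of day 14 against day 1 and 25 for the agreeing arrays of 1.0 µg/L. The numbers were checked for pairing across groups. Residuals of arrays with the same number had a median Pearson r across probes of 0.025 (100 pairs, lowest -0.386, 30 over 0.1). It was -0.002 for the other pairs. Pairing by day or treatment was not tested, and the block was not used elsewhere.

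Leaving out each array in turn, the limma count of 1.0 µg/L against control on day 1 ranged from 0 (without EE2 1.0 µg/L of day 1, replicate 1, 787 unadjusted) to 24 (without control of day 14, replicate 1). That of day 7 ranged from 3 (without control of day 7, replicate 2) to 41 (without control of day 14, replicate 1). Day 14 gave 120 (without EE2 1.0 µg/L of day 14, replicate 2) to 2609 (without control of day 14, replicate 2). For the higher dose the range was 0 (without EE2 10.0 µg/L of day 1, replicate 2, 480 unadjusted) to 10 (without control of day 14, replicate 1) on day 1. On day 7 it was 743 (without EE2 10.0 µg/L of day 7, replicate 1) to 2706 (without control of day 14, replicate 1). Day 14 gave 3256 (without EE2 10.0 µg/L of day 14, replicate 1) to 5352 (without control of day 14, replicate 1) there. Counts between doses went from 1 (without EE2 10.0 µg/L of day 1, replicate 3) to 127 (without EE2 1.0 µg/L of day 14, replicate 1) on day 1. On day 7 they went from 1030 (without EE2 10.0 µg/L of day 7, replicate 1) to 3614 (without control of day 14, replicate 1). Doses of day 14 differed at 3360 (without EE2 10.0 µg/L of day 14, replicate 1) to 6323 (without control of day 14, replicate 1). The 1.0 µg/L effect over time went from 24 (without control of day 1, replicate 2) to 1689 (without control of day 14, replicate 2). For 10.0 µg/L this was 1870 (without EE2 10.0 µg/L of day 1, replicate 2) to 3909 (without control of day 14, replicate 1). The mean over days went from 161 (without control of day 1, replicate 2) to 494 (without control of day 14, replicate 1) for 1.0 µg/L. Its 10.0 µg/L count was 2435 (without EE2 10.0 µg/L of day 1, replicate 3) to 4513 (without control of day 14, replicate 1). Controls of days 7 and 1 differed at 22 (without control of day 7, replicate 1) to 51 (without control of day 14, replicate 1). Those of days 14 and 1 did at 166 (without control of day 1, replicate 3) to 3164 (without control of day 14, replicate 2). The agreeing arrays gave 15 (without control of day 1, replicate 3) to 393 (without EE2 10.0 µg/L of day 14, replicate 1) for 1.0 µg/L. Their 10.0 µg/L count was 3519 (without control of day 1, replicate 3) to 5428 (without EE2 10.0 µg/L of day 14, replicate 3). Between doses they gave 3690 (without EE2 1.0 µg/L of day 7, replicate 2) to 5205 (without EE2 10.0 µg/L of day 14, replicate 3). Of these cases 71 of the scanner-file assignment, 9 of the agreeing arrays and 55 of the value-table assignment moved a count by over 1.5 times, and 319, 18 and 320 did not. Named receptors lost the call in 98, 32 and 132 cases, gained one in 12, 0 and 1, and changed sign in none. Where 1 of 2 arrays was left out (EE2 10.0 µg/L of day 1, and the control of day 14 with the value-table assignment), the lone array was assumed to vary like the other groups.

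Signal over background limited the tests: 19 of the 70 receptor names were not tested. For probes below background in a group only a lower bound of the fold could be given. The low-signal array of the control of day 14 lay in the group against which all day 14 effects of the scanner-file assignment were measured.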

Other observations

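The slides were filled in a different order under each assignment. With scanner-file samples, the slide of 8 arrays held controls of days 1, 7 and 14, while with value-table samples its matched arrays were of day 1, from all 3 treatments. The slide of EE2 10.0 µg/L on day 14 (3 arrays) and the slide with 1 array (EE2 1.0 µg/L on day 7) were the same under both.

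Probes of identical sequence under 2 names gave a measure of the repeatability within an array. Over 35 such pairs the median SD of their log2 difference over arrays was 0.153, against a median residual SD of 0.385 between arrays of a group with the scanner-file assignment.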
